A study of Homo sapiens with 4 samples.

How the data were processed

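ATAC-seq was done on 2 samples of H1 human embryonic stem cells (hESC) and 2 samples of H1-derived human trophoblast stem cells (hTSC), per the labels. The authors deposited 1 peak list per cell type, made from both samples of that type per the series design text, so samples cannot be compared with each other and leaving a sample out was not possible. Per the submitters' processing notes, the tools were cutadapt 1.13, Bowtie2 2.2.5, SAMtools 1.3.1, Picard 1.90, MACS2, deepTools 2.4.2 and HOMER, listed without role or parameters, on build hg38. Versions of MACS2 and HOMER, the shift of read ends for the transposase, the treatment of duplicates and of reads with several alignments, and any excluded regions are not given in the sources used here. Such filters decide which regions can carry a peak at all.

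Each deposited peak has a position, a score, a fold enrichment (a ratio of the summit over the peak caller's background), a −log10 p, a −log10 q and a summit, all the authors' own values in narrowPeak format. The deposited score equals 10 times −log10 p, capped, in 99.998% of hESC and 100.0% of hTSC peaks. Every deposited −log10 q was at least 5, which is the authors' threshold as the values show it. Median fold was 4.55 in hESC and 5.71 in hTSC, and median −log10 q was 10.3 and 16.4. These values depend on depth, which is unknown since the lists hold no read counts, and were used to rank, filter or describe peaks within a list. Only the check on chromosome 2 in the closing section sets fold in the lists against each other, to compare chromosomes. A deeper or cleaner library gives a longer list, so the number of peaks called in one list only partly reflects how much was called. For this reason both lists were also compared at equal length. Peaks within a list did not overlap, and all lay on the 24 main chromosomes.

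A peak was called shared when it overlapped a peak of the other list by at least 1 bp, and otherwise hESC-only or hTSC-only. Overlap of hESC peaks by chance was estimated from 100 circular shifts of the hTSC list along each chromosome. Shares carry 95% Wilson intervals, which cover counting error only. The NCBI RefSeq gene table of GRCh38.p14, the same build, gave the spans of 20037 protein-coding genes. It holds no strand, transcript starts or exons, and no genome sequence was used here. The design fixed before the data were examined used transcription start sites, and was changed as follows. A gene end is a window of 1 kb around either end of a gene's span, so it includes the far end of the gene as well as its start. Other peaks were assigned to gene bodies or intergenic space by their midpoint, without exon or intron. The effect of the missing strand was checked on 564 genes that have a named divergent transcript, which shows the start side. Of these, 89.2% had an hESC peak at the start side and 1.60% at the far side only, with 85.5% and 1.95% in hTSC. Most of these genes thus had a start-side peak, so the rates need not hold for genes with an end peak in 1 list only. The latter were 9.03% (hESC only) and 5.88% (hTSC only) of all genes, and how many of their peaks lie at the far end is unknown. Motif content and base composition of peaks, also planned, were not analysed here.

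For each gene the cell-type-only peaks within 50 kb of its span were counted. A list's mean of hTSC-only minus hESC-only peaks was placed among 10000 random gene lists of the same size, matched on the total number of peaks per locus in 20 bins. A list outside percentiles 2.5 to 97.5 is said to stand apart from matched lists. This describes these 2 peak lists and is no test of the cell types, and no p-value was computed. On simulated lists of 20 genes, the procedure found 26.0% of lists given 1 extra hTSC-only peak per gene, 69.5% of those given 2 and 100.0% of those given 4. It placed 7% of unchanged lists outside. The simulation used fewer random lists, and added the extra peaks to the difference but not to the total used for matching. A real extra peak also raises that total, so these rates can overstate what the procedure finds. Genes of 1 cluster share windows and are not independent, which makes such percentiles more extreme than for separate genes.

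The 18 gene lists, with 351 entries and 340 different genes, were fixed before the data were examined. All entries were found in the gene table, 2 of them by an older symbol (TDGF1 and SLC22A18). Named genes follow a rule fixed at the same time. From each list up to 6 members were taken, first those with an end peak in 1 list only and then those with the largest difference in their window. The 10 genes per direction with most cell-type-only peaks, where the other class has at most 0.25 times as many, and the 5 strongest distal peaks per direction were added. Exceptions are stated where they occur. X and Y were left out of the comparison of chromosomes.

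Alternatives were a −log10 q of at least 10, lists of equal length (the strongest peaks), an overlap of at least 50% of both peaks, a distance of up to 500 bp in place of overlap, end windows of 500 and 2500 bp, locus windows of 20 and 100 kb, and assignment of all peaks within 50 kb. Leaving out chromosomes 2 and 20, and leaving out genes in peak-free stretches (at least 300 kb and 10 protein-coding genes without a peak in either list), were added after seeing the data, as was joining trophoblast list members whose 50 kb windows overlap to 1 locus, in which an end peak of any member counts. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9.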

Results

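Open chromatin was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in human embryonic stem cells and human trophoblast stem cells. The embryonic stem cells (hESC) were the established line H1, and the trophoblast stem cells (hTSC) were derived from H1. Trophoblast forms the outer layer of the embryo and later the epithelium of the placenta, and the series concerns the conversion of pluripotent cells into its stem cells. There were 4 samples, 2 per cell type, and the deposited values were 1 list of accessible regions (peaks) per cell type, each made from both of its samples. The spread between replicates is therefore not in these values, no test between the cell types was possible, and intervals given here cover counting error only. Read depth is unknown, since the lists carry no read counts.

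The question the design poses is which regions are accessible in trophoblast stem cells and which in embryonic stem cells. The hESC list held 58682 peaks covering 32.5 Mb and the hTSC list held 83219 peaks covering 41.2 Mb. Of the hESC peaks, 25975 overlapped an hTSC peak by at least 1 bp, or 44.3% (95% Wilson interval 43.9 to 44.7%). The average was 2.99% when the hTSC list was shifted along the chromosomes. The other 32707 were called in hESC only. Of the hTSC peaks, 25977 were shared, or 31.2% (30.9 to 31.5%), and 57242 were called in hTSC only. Stronger peaks were shared more often: across 4 equal groups of peaks by −log10 q, the share rose from 23.1% in the weakest hESC group to 72.8% in the strongest, and from 18.7% to 49.7% in hTSC. A peak called in one list only is one that did not reach the authors' threshold in the other list, which does not show closed chromatin there. The excess of hTSC-only peaks remained with the stricter threshold. With only peaks of −log10 q of at least 10, 14679 were hESC-only and 40454 hTSC-only. The −log10 q itself depends on depth, so a deeper hTSC library could give such an excess. With lists of equal length the counts were 37240 and 37428. Equal lengths with nearly equal numbers of shared peaks make these counts nearly equal by construction, so they cannot inform on the excess.

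Shared peaks lay at the ends of protein-coding genes far more often than peaks called in one cell type. Within 1 kb of an annotated gene end lay 40.6% of the shared hTSC peaks (40.0 to 41.2%), 9.45% of the hESC-only peaks (9.14 to 9.78%) and 5.05% of the hTSC-only peaks (4.88 to 5.23%). Gene bodies held 43.6% of hESC-only and 47.2% of hTSC-only peaks, and 47.0% and 47.7% were intergenic. Shared peaks were also stronger, with a median −log10 q of 15.1 against 8.23 for hESC-only and 28.1 against 13.4 for hTSC-only peaks. The gene-end share rose with strength, from 11.6% in the weakest to 43.6% in the strongest hESC group, and from 7.12% to 32.8% in hTSC. Sharing and strength were not separated here. The hESC-only share at gene ends exceeded the hTSC-only share under every alternative tried. The size of the hTSC-only share moved by over 1.5 times with the stricter threshold (7.93%) and with end windows of 500 bp (3.15%) or 2500 bp (9.83%).

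**Figure D1:**
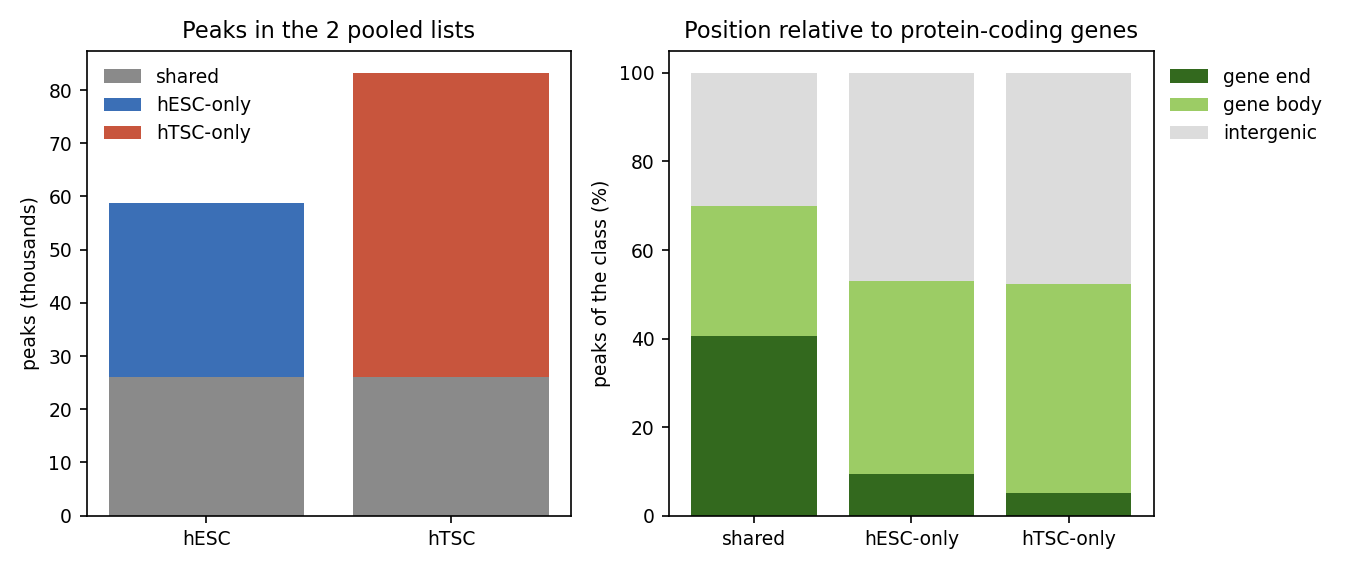
Left, number of peaks (axis in units of 1000) in the hESC and hTSC lists, divided into peaks that overlap the other list (grey) and peaks called in hESC only (blue) or hTSC only (red). Right, percent of shared hTSC peaks, hESC-only peaks and hTSC-only peaks at gene ends, in gene bodies and between genes, where the gene-end share is 40.6% for shared peaks, 9.45% for hESC-only and 5.05% for hTSC-only peaks.

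Most genes with an accessible end had one in both cell types. Of 20037 protein-coding genes, 11422 had an end peak in both lists, 1810 in hESC only, 1178 in hTSC only and 5627 in neither. The order of the hESC-only and hTSC-only classes depended on the peak threshold: with −log10 q of at least 10, 1334 genes had an end peak in hESC only and 2151 in hTSC only. Genes with no peak in either list included 641 that lie in 24 gene-rich stretches of the genome where neither list has any peak, and 1 gene of those stretches had an end peak in hESC only.

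Genes of the pluripotency network had end peaks in both cell types, in hESC only or in neither. Among 27 genes of primed and general pluripotency, 8 had an end peak in both lists, 10 in hESC only, 9 in neither and 0 in hTSC only. The 10 were the transcription factor genes SOX2, NANOG, PRDM14, FOXD3 and ZIC3, the germline and pluripotency gene DPPA4, the signalling genes GDF3 and TDGF1, the WNT antagonist SFRP2, and USP44. Around DPPA4 (chromosome 3, 109326144 to 109339636, hg38) 6 peaks were called in hESC only within 50 kb and 0 in hTSC only. The corresponding counts were 7 and 1 around SFRP2, 5 and 1 around SOX2 (chromosome 3, 181711925 to 181714436), 5 and 1 around PRDM14 (chromosome 8, 70051651 to 70071252), 4 and 0 around FOXD3, and 1 and 3 around GDF3. The strongest hESC-only peak near SOX2 was intergenic, at 181756604 to 181757129, with a fold enrichment of 6.48 in the authors' list. POU5F1, which encodes OCT4, had no peak in either list and lies in the largest peak-free stretch, so nothing can be read from these lists about its accessibility. POU5F1, NANOG, TDGF1, ZIC3 and USP44 were named after their values were seen. Over the list, 14 genes had more hESC-only and 9 more hTSC-only peaks within 50 kb. Their windows held 94 peaks of each kind, counting each peak once. The difference, hTSC-only minus hESC-only peaks within 50 kb, averaged −0.26 per gene. This stood at percentile 0.13 of 10000 random gene lists with as many peaks, whose central 95% ran from 0.41 to 2.89.

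Genes of naive pluripotency, the earlier state of the epiblast, did not follow that pattern. Of 11 genes, 4 had an end peak in both lists, 1 in hTSC only, 6 in neither and 0 in hESC only. The gene with the hTSC-only end was DPPA3, with 2 hESC-only and 4 hTSC-only peaks within 50 kb. It neighbours GDF3, so both genes share part of their windows. The transcription factor gene TFCP2L1 had 1 hESC-only and 12 hTSC-only peaks, KLF4 had 0 and 9, and KLF5 had 1 and 6, while KLF17 had 4 and 2. TFCP2L1 lies on chromosome 2, which held an excess of hTSC-only peaks along its length. The mean difference was 2.82 peaks per gene, at percentile 89.88. It was 97.98 with windows of 100 kb, 70.5 with windows of 20 kb and 75.31 without chromosomes 2 and 20.

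Trophoblast genes were the counterpart. In the list of trophoblast stem cell and cytotrophoblast genes, 17 of 24 had an end peak in both lists, 5 in hTSC only, 2 in neither and 0 in hESC only, and all 24 had more hTSC-only than hESC-only peaks within 50 kb. The 5 were GATA3 and CDX2, which encode transcription factors of trophoblast specification, the TEAD cofactor gene VGLL1, the nuclear receptor gene NR2F2 and the endocytic receptor gene LRP2. Around GATA3 (chromosome 10, 8045333 to 8075198) 14 peaks were called in hTSC only and 0 in hESC only, and around VGLL1 (chromosome X, 136532215 to 136556799) 10 and 0. LRP2 had 20 hTSC-only and 3 hESC-only peaks and lies on chromosome 2. CDX2 and NR2F2 each had 6 hTSC-only and 2 hESC-only peaks. EGFR, the receptor of epidermal growth factor, had an end peak in both lists, with 28 hTSC-only and 3 hESC-only peaks in its window. The mean difference was 8.79 peaks per gene, at percentile 100 of the random lists, whose central 95% ran from 1.79 to 5.83.

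Syncytiotrophoblast genes, which serve the hormone-producing fused layer of the placenta, had the most ends called in hTSC only, 13 of 28. A further 6 had an end peak in both lists and 9 in neither. Those 13 included GCM1, a transcription factor gene of syncytial fusion, the steroid synthesis genes CYP19A1, CYP11A1 and HSD3B1, and the chorionic gonadotropin genes CGB5 and CGB8. Around CYP19A1 (chromosome 15, 51208057 to 51338596) lay 14 hTSC-only and 2 hESC-only peaks, and around CYP11A1 14 and 4. GCM1 (chromosome 6, 53126961 to 53148841) and HSD3B1 each had 9 and 0. CGB5 and CGB8 had 8 hTSC-only peaks each, with 2 and 3 hESC-only peaks, but they are near-identical neighbouring copies whose windows overlap, and so do not count as separate observations. The list's mean difference of 5.0 stood at percentile 99.75, and at 91.44 with windows of 100 kb.

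Extravillous trophoblast genes, those of the invasive placental cells, showed no such shift at gene ends. Of 17 genes, 7 had an end peak in both lists, 8 in neither, 0 in hTSC only and 2 in hESC only, namely the gelatinase gene MMP2 and the VEGF receptor gene FLT1. The windows of ASCL2 (12 hTSC-only and 2 hESC-only peaks), FN1 (11 and 1), ITGA1 (8 and 2) and SERPINE1 (9 and 3) held more hTSC-only peaks. FN1 lies on chromosome 2, and HLA-G, named after its values were seen, lies in the largest peak-free stretch. Over the list the mean difference of 3.0 stood at percentile 73.38. Across these 3 trophoblast lists together, 18 of 69 genes had an end peak in hTSC only, or 26.1%, and 2 in hESC only, against 5.88% and 9.03% of all protein-coding genes. With members whose windows overlap joined to 1 locus, CGB5 and CGB8 among them, 15 of 63 loci had such ends in hTSC only, or 23.8% (14.99 to 35.64%), and 2 in hESC only. The counts of genes were 13 and 4 with lists of equal length, where 875 and 2424 of all genes had such ends, and 21 and 4 with the stricter threshold, where 2151 and 1334 did.

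**Figure D2:**
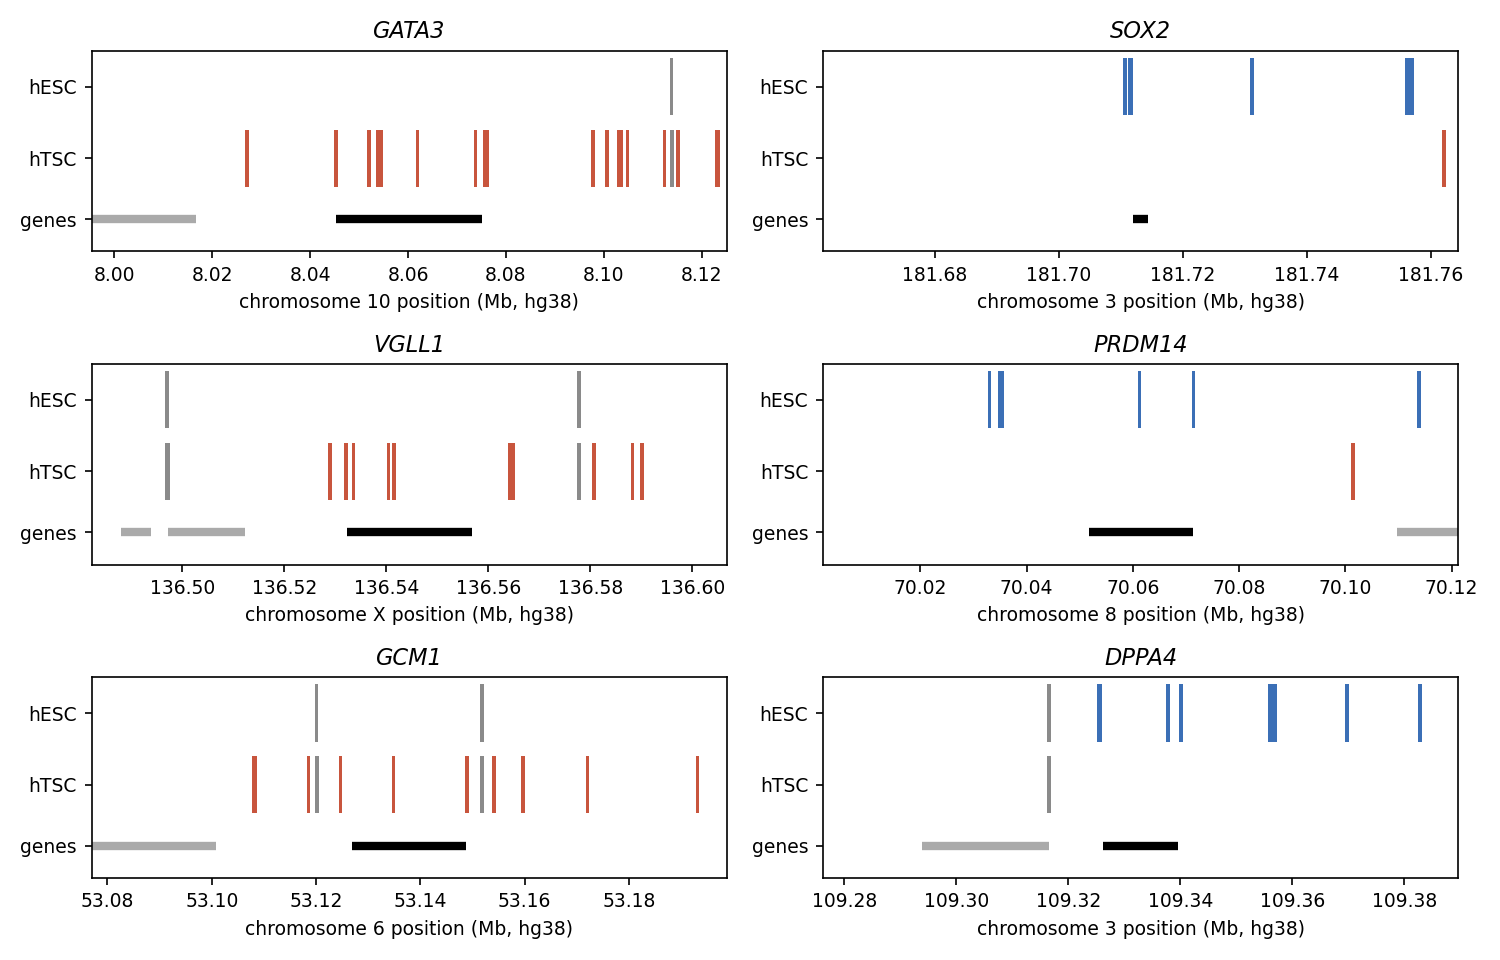
Peaks (vertical bars) within 50 kb of GATA3, VGLL1, GCM1, SOX2, PRDM14 and DPPA4, with the position in Mb on hg38 along the horizontal axis, the named gene in black and neighbouring protein-coding genes in light grey. Blue bars are hESC-only, red bars hTSC-only and dark grey bars shared peaks, and the window of GATA3 holds 14 hTSC-only peaks while that of DPPA4 holds 6 hESC-only peaks.

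Amnion, another extraembryonic epithelium that can arise from primed pluripotent cells, gave a mixed picture. Of 12 genes, 3 had an end peak in both lists, 4 in hTSC only (ITGB6, WNT6, VTCN1 and GABRP), 2 in hESC only (DLX5 and IGFBP3) and 3 in neither. The integrin gene ITGB6 had 21 hTSC-only and 1 hESC-only peaks, WNT6 had 9 and 2, and both lie on chromosome 2. VTCN1 had 7 and 1, whereas DLX5 had 1 and 7. The mean difference of 3.42 stood at percentile 92.81. It passed the upper limit with the stricter threshold (98.48) and with lists of equal length (99.35), and was 80.18 with windows of 20 kb. Without chromosomes 2 and 20, which removes 3 members, the percentile was 63.56.

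Neuroectoderm genes leaned toward hESC. Of 14 genes, 3 had an end peak in both lists, 3 in hESC only (SOX3, SIX6 and NEUROG2), 1 in hTSC only (OTX1) and 7 in neither. ZIC1, which had no end peak in either list, had 9 hESC-only and 0 hTSC-only peaks in its window, and PAX6 had 4 and 0. OTX1, on chromosome 2, had 4 of each. The mean difference of −1.71 stood at percentile 0.04, and at 2.55 with the stricter threshold, just inside the central 95%.

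Mesoderm and endoderm genes did not stand apart as a list (mean difference 1.5, percentile 71.18). Of 16 genes, 6 had an end peak in both lists, 5 in neither, 4 in hESC only and 1 in hTSC only. Those called in hESC only were the primitive streak genes MIXL1 and GSC, the early mesoderm gene MESP2 and the nodal antagonist gene CER1. Their windows mostly leaned the other way: MESP2 had 2 hESC-only and 8 hTSC-only peaks, CER1 1 and 3, and MIXL1 1 and 2, while GSC had 3 and 1. GATA6, a transcription factor gene of endoderm and also of other lineages, had the hTSC-only end, with 13 hTSC-only and 0 hESC-only peaks in its window (chromosome 18, 22169589 to 22202528). Mesenchyme and fibroblast genes, which would mark feeder or stromal cells, did not stand apart either (1.67, percentile 71.97), but with the stricter threshold the percentile was 97.46, just inside the central 95%. Of 15 genes, 5 had an end peak in both lists, 3 in hTSC only (VIM, PDGFRA and TWIST2), 1 in hESC only (PRRX1) and 6 in neither. TWIST2, on chromosome 2, had 7 hTSC-only and 0 hESC-only peaks.

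Epithelial adhesion and keratin genes had more hTSC-only peaks than matched random lists. Of 27 genes, 19 had an end peak in both lists, 4 in hTSC only (LAMA5, ESRP2, ST14 and OVOL1), 1 in hESC only (LAMA3) and 3 in neither. The tight junction gene CLDN4 had 14 hTSC-only and 2 hESC-only peaks in its window, the laminin gene LAMA3 had 16 and 5, and LAMA5, on chromosome 20, had 9 and 0. The mean difference was 4.89 peaks per gene, at percentile 99.10. That percentile fell inside the central range with windows of 20 kb (84.32) and without chromosomes 2 and 20 (97.44).

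Among pathway lists, Hippo and TEAD genes had end peaks in both lists for 15 of 22 members, in hTSC only for 4 (TEAD3, AMOTL1, AJUBA and VGLL1), in hESC only for 1 (VGLL4) and in neither for 2. The TEAD1 window held 22 hTSC-only and 4 hESC-only peaks and that of AMOTL1 held 18 and 5. Their mean difference of 5.77 stood at percentile 94.50, and at 98.37 with the stricter threshold. BMP, activin and nodal genes (29 genes, 2.76, percentile 40.46) had end peaks in both lists for 20, in neither for 5, in hESC only for BMPR1B, SMAD1 and SMAD9, and in hTSC only for SMAD7. The BMPR1B window held 11 hESC-only and 4 hTSC-only peaks, and the SMAD3 window held 5 and 20. WNT pathway genes (22 genes, 3.64, percentile 88.12) had end peaks in both lists for 12, in hESC only for 5 (WNT5A, WNT10A, LGR5, LEF1 and SFRP2), in hTSC only for 3 (WNT6, WNT7B and TCF7) and in neither for 2. LGR5 and TCF7 were named after their values were seen. With the stricter threshold the WNT percentile was 99.31.

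Imprinted genes, expressed from 1 parental copy and prominent in placenta, had 5 of 17 ends accessible in both lists, 3 in hTSC only (IGF2, GRB10 and NDN), 2 in hESC only (KCNQ1 and SNRPN) and 7 in neither. GRB10 had 21 hTSC-only and 7 hESC-only peaks, and ZFAT 19 and 5. Their mean difference of 3.88 stood at percentile 98.48, but inside the central range with the stricter threshold (84.51), lists of equal length (88.84) and windows of 20 kb (91.96). HOX genes had 4 of 23 ends in both lists, 5 in hTSC only, 3 in hESC only and 11 in neither (mean difference 1.04, percentile 76.68). Neighbouring HOX genes share windows, and the percentile varied widely, from 21.8 with lists of equal length and 45.54 with windows of 100 kb to 99.88 with the stricter threshold. It was 98.61 without chromosomes 2 and 20, which removes 5 HOXD genes that had 2 or 3 hESC-only and 0 hTSC-only peaks each. Regulators of DNA methylation and Polycomb marks had 11 of 15 ends in both lists, 2 in hTSC only (TET3 and CBX7), 2 in neither and 0 in hESC only (4.87, percentile 79.66). TET3, on chromosome 2, had 19 hTSC-only and 1 hESC-only peaks.

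Antigen presentation genes could largely not be assessed, since 9 of 13 lie in peak-free stretches of chromosome 6, HLA-A and HLA-B among them. Of the list, 2 had an end peak in both lists, 1 in hESC only (NLRC5), 0 in hTSC only and 10 in neither (mean difference 0.77, percentile 50.48). Housekeeping genes, the control list, had 17 of 19 ends accessible in both lists and 0 in one list only. The remaining 2, RPS18 and TUBB, lie in peak-free stretches and were named after their values were seen. This list's mean difference of 2.11 stood at percentile 30.12, close to the mean of 2.08 over all protein-coding genes. With 18 lists compared, 4 stood above and 2 below the central 95% of their random lists. In simulated lists without any planted difference, 7% fell outside that range.

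**Figure D3:**
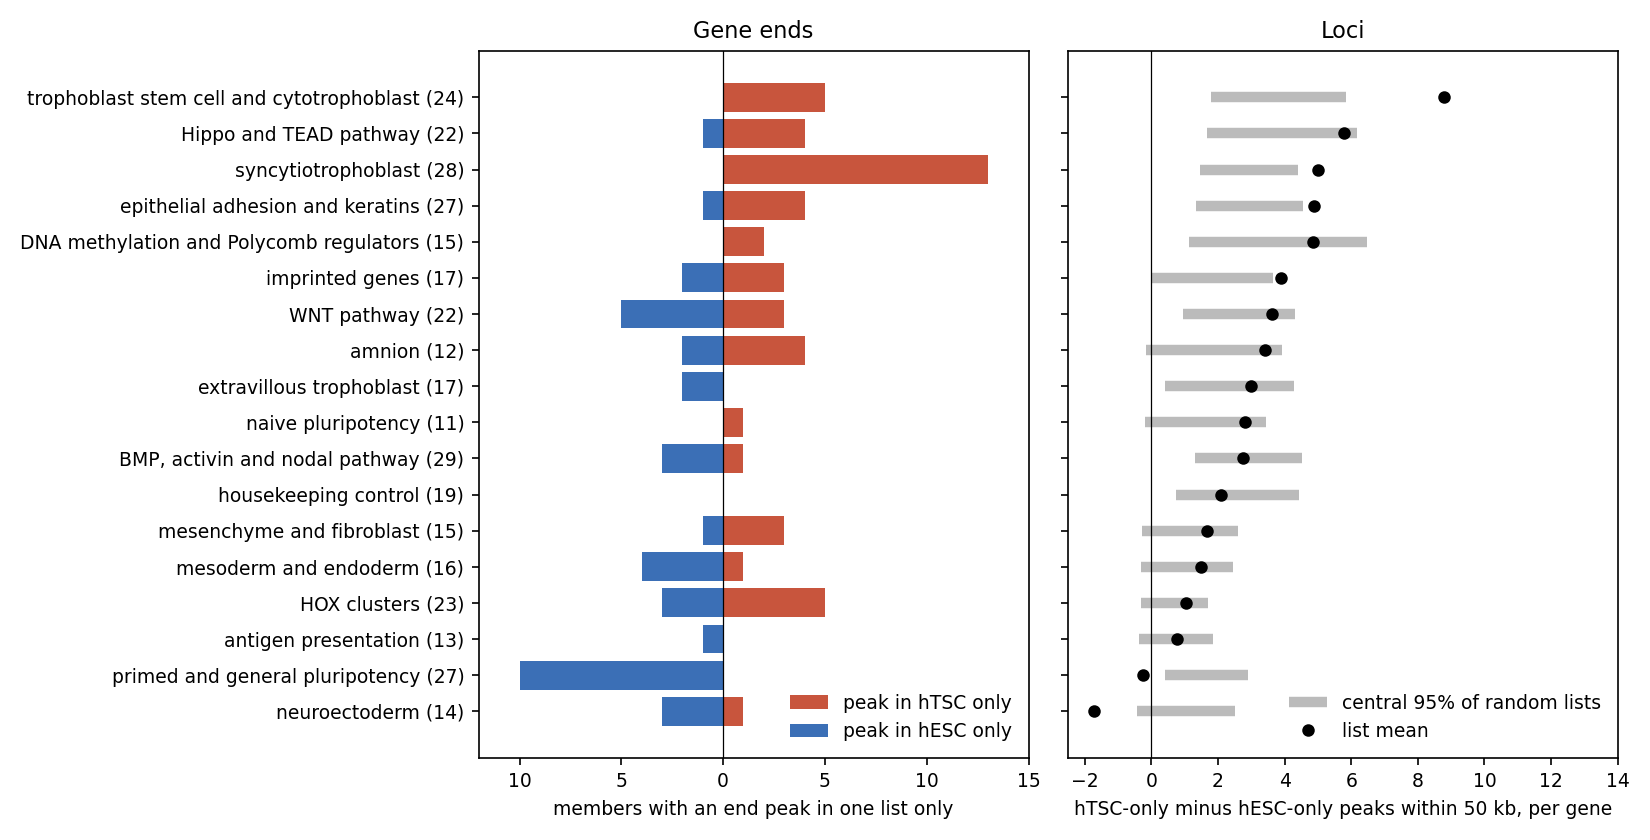
For 18 gene lists fixed before the data were examined, left, the number of members with an end peak in hTSC only (red, to the right) or hESC only (blue, to the left), with the number of genes in parentheses. Right, the mean number of hTSC-only minus hESC-only peaks within 50 kb per gene (black points) against the central 95% of 10000 matched random lists (grey bars), with the trophoblast stem cell list at 8.79 and the neuroectoderm list at −1.71.

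Counting each peak at its nearest protein-coding gene within 100 kb, CSMD1 (chromosome 8, 2935361 to 4994914) led the hESC direction with 36 hESC-only and 3 hTSC-only peaks. OPCML had 33 and 7, NTM 29 and 2, AUTS2 28 and 7, CNTNAP2 28 and 5, and GRID2 28 and 4. The remaining 4 of the 10 were ROBO2 (21 and 5), TMEM132D (21 and 1), FAT3 (20 and 2) and BNC2 (19 and 3). In the hTSC direction, TNS3 (chromosome 7, 47275154 to 47582586), which encodes a focal adhesion protein, had 42 hTSC-only and 6 hESC-only peaks. GLIS3 had 40 and 8, PTPRM 40 and 10, ASAP1 35 and 5, CTIF 35 and 8, BCAR3 34 and 5, PRKCH 34 and 6, and SETBP1 34 and 5. FMNL2 (33 and 2) and PRKCE (33 and 5) lie on chromosome 2. Which genes led depended on the threshold: of the 10 per direction, 5 hESC and 3 hTSC genes were kept with the stricter one, where ROBO2 had 5 peaks of each kind by this count. In its 50 kb window, ROBO2 had 20 hESC-only and 5 hTSC-only peaks, and 4 and 5 with the stricter threshold.

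The strongest peaks away from gene ends that were called in one list only were mostly intergenic. By the authors' fold enrichment, those in hESC included 13:72062332 to 72063162, at 15.96-fold and 195543 bp from DACH1, and 8:32927678 to 32928389, at 14.9-fold and 153988 bp from NRG1. Others lay 15370 bp from NFIB (14.7-fold) and in the body of PRIM2 (13.99-fold). The highest value, 25.5-fold, belonged to a peak at 17:22524301 to 22524587, which is 819832 bp from its nearest gene KCNJ18. Its −log10 q was 1237.5, far above the 67.7 to 122.2 of the other hESC peaks named here. No filter for regions prone to alignment artifacts was applied here, so an artifact was not excluded for this or any other peak in this paragraph. In hTSC the highest was 29.8-fold at 9:63342565 to 63342855, 296626 bp from LOC107987004. Next came a peak 25072 bp from STAM2 on chromosome 2 (28.0-fold), and peaks in the body of MPDZ (27.6-fold), 155944 bp from CD96 (26.8-fold) and in the body of CLSTN2 (26.7-fold). These fold enrichments give a peak's rank within its own list, and those of hESC and hTSC peaks are not set against each other.

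Chromosome 2 held more hTSC-only peaks than any other autosome relative to its hESC-only peaks. It carried 6519 hTSC-only and 2407 hESC-only peaks, a ratio of 2.71, or 11.4% of all hTSC-only peaks (11.1 to 11.7%) and 7.36% of hESC-only peaks (7.08 to 7.65%). The ratio was 2.28 on chromosome 20 and 2.13 on chromosome 21, and from 1.47 to 1.903 on the other 19 autosomes. With the stricter threshold and with lists of equal length, the ratio on chromosome 2 remained 1.55 times that of the other autosomes.

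**Figure D4:**
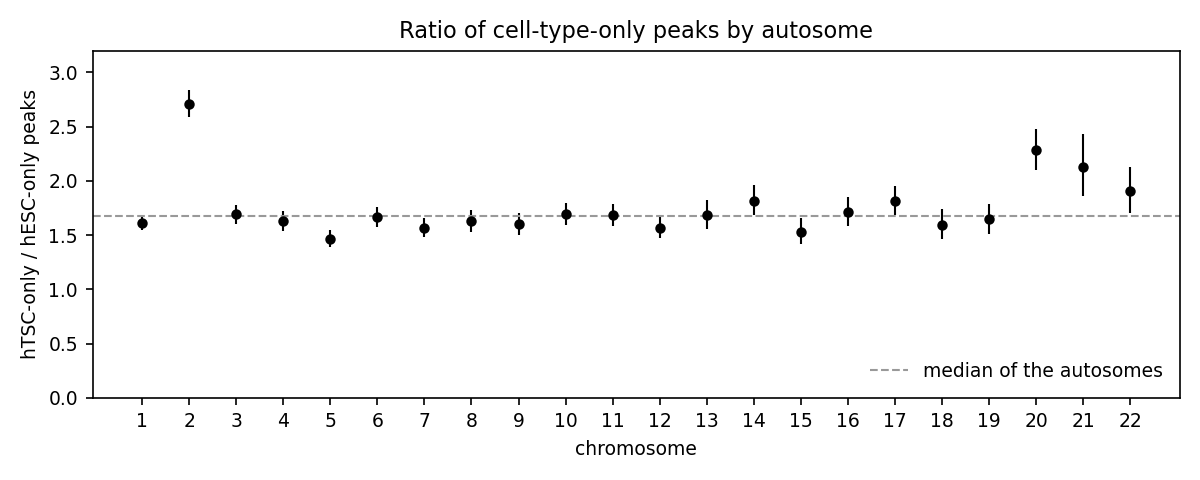
Ratio of hTSC-only to hESC-only peaks (vertical axis, no unit) for each of the 22 autosomes, with 95% intervals from counting error as vertical lines and the median of the autosomes, 1.67, as a dashed line. Chromosome 2 lies at 2.71, followed by chromosome 20 at 2.28.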

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

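Leaving out chromosomes 2 and 20 or genes in peak-free stretches, and joining neighbouring members of the trophoblast lists, were chosen after seeing the data. No paired analysis was possible because each peak list pools both replicates, and for the same reason no replicate could be left out. Use of the 5-prime-most start site and all alternatives for motif content and base composition were not run, for want of strand and genome sequence. Depth is unknown, so a peak missing from a list cannot be told from one below its detection limit. Of 144 percentiles of gene lists under alternatives, 130 kept their side of the central range. Of 810 values for 135 named genes, 737 kept an hTSC-only share inside the Wilson interval of the main setting or had no such peaks left. A further 72 moved and 1 reversed. Reversal was counted only where the main interval excluded an equal split, so other changes of sign are among the values that stayed or moved. Windows with few peaks have wide intervals, so staying inside them says little. The pluripotency list stayed below and the trophoblast stem cell list above its random lists under all alternatives run. The cause of the changes below was not tested, except that the stricter threshold and equal lengths remove peaks by construction.

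With −log10 q of at least 10, hESC peaks numbered 30187 and hESC-only peaks 14679, and 51.4% of hESC and 27.8% of hTSC peaks were shared. At gene ends lay 11.6% of hESC-only, 7.93% of hTSC-only and 52.7% of shared hTSC peaks. Genes with an hTSC-only end numbered 2151, and the difference from hESC-only genes reversed from −632 to 817. Percentiles were 98.48 for amnion, 2.55 for neuroectoderm, 97.46 for mesenchyme and fibroblast, 98.37 for Hippo and TEAD, 99.31 for WNT, 84.51 for imprinted and 99.88 for HOX genes. the 50 kb window of ROBO2 reversed to a difference of 1, while the count at the nearest gene gave 5 of each, the chromosome 2 ratio relative to other autosomes was 1.55, and 5 hESC and 3 hTSC leading loci were kept. With equal list lengths, 36.5% of hESC and 36.2% of hTSC peaks were shared, hTSC-only peaks numbered 37428, gene ends held 10.3% of hESC-only and 45.6% of shared hTSC peaks, and the gene-end difference was −1549. Percentiles were then 99.35 for amnion and 88.84 for imprinted genes, the chromosome 2 value was 1.55, and 6 and 3 loci were kept.

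With 50% overlap, 36.9% of hESC and 26.0% of hTSC peaks were shared, and gene ends held 12.4% of hESC-only, 7.12% of hTSC-only and 41.8% of shared hTSC peaks. With a distance of 500 bp, these were 46.6%, 33.4%, 8.41%, 4.25% and 39.9%. End windows of 500 bp gave gene-end shares of 7.07%, 3.15% and 37.4%, and windows of 2500 bp gave 13.8%, 9.83% and 45.4%, with a gene-end difference of −484. Locus windows of 20 kb gave percentiles of 84.32 for epithelial and 91.96 for imprinted genes, and windows of 100 kb gave 97.98 for naive pluripotency and 91.44 for syncytiotrophoblast. Counting all peaks within 50 kb kept 6 of the hTSC loci. Without chromosomes 2 and 20, 32.0% of hTSC peaks were shared, and the percentiles were 97.44 for epithelial and 98.61 for HOX genes. With neighbouring members joined, the 3 trophoblast lists had 15 loci with hTSC-only and 2 with hESC-only ends, in place of 18 and 2 genes.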

Other observations

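Gene families and microRNA clusters in the next paragraph, and the tests on peak-free stretches and chromosome 2, were chosen after the results were seen. The tests on long genes were written before their values were computed, but after the leading loci had been seen.

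Of 21 gene families examined, some of whose members are also in the lists of the report, 10 stood below the central 95% of matched random lists, 1 stood above and 10 inside, among them TFAP2 (percentile 66.48), GRHL (87.6), TEAD (66.2) and KLF (45.14). Below means fewer hTSC-only relative to hESC-only peaks than in matched lists, and 3 of the 10 still had more hTSC-only peaks in their windows: ZNF (477 genes, 1285 hTSC-only and 718 hESC-only, percentile 0.02), FOX (186 and 148, percentile 1.14) and KCN. The 53 clustered protocadherin genes, which encode neuronal adhesion proteins, had 293 hESC-only and 94 hTSC-only peaks summed over their windows, with 26 ends called in hESC only and 1 in hTSC only, but they share windows in 1 region. The 5 ZIC genes had 29 and 3. Peak counts of all these families are sums over the windows of their members. A peak in the overlapping windows of neighbouring members therefore counts once for each of them. Among 95 potassium channel genes (KCN), 33 had an end peak in hESC only and 3 in hTSC only, and their windows held 388 hESC-only and 403 hTSC-only peaks, a mean difference of 0.16 per gene against a median of 2.28 in matched lists (percentile 0). Among 23 cadherin genes (CDH) these ends numbered 10 and 0, with 134 hESC-only and 113 hTSC-only peaks (percentile 0.01). The 6 GATA genes had 49 hTSC-only and 11 hESC-only peaks, at percentile 99.87 of matched lists. At the MIR302 and MIR367 cluster, expressed in pluripotent cells, 3 peaks within 10 kb were called in hESC only and 0 in hTSC. The placental microRNA cluster C19MC had 4 hESC and 6 hTSC peaks, of which 1 and 3 were not shared. MIR371 to MIR373 had 2 and 5, of which 1 and 4 were not shared. MIR200C and MIR141 had 3 and 3, all shared, and MIR200B, MIR200A and MIR429 had 3 and 2, with 1 in each list not shared.

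In 24 gene-rich stretches, 40.0 Mb with 642 protein-coding genes, neither list had a peak, and the largest, 6:28507283 to 32559846, holds 135 genes, POU5F1 among them. Closed chromatin as the cause of every stretch is argued against by the kind of gene inside: ribosomal, proteasome, general transcription factor and RNA polymerase genes made up 9 of the 641 genes without an end peak inside the stretches and 6 of 4986 outside, a ratio of shares of 11.7 (4.17 to 32.7). Those 9 lie in 5 stretches, so the interval, which treats genes as independent, can be too narrow. The families were taken by gene symbol, and whether each member is accessible in every cell type was not checked. Closed chromatin as the cause stays open for the other stretches. Removal of reads that align to several copies of a region in the assembly, such as alternate haplotypes, may be the reason, but the 0 peaks found on other contigs go with it without deciding it, since a list limited to the main chromosomes would give the same. No biological explanation was tested further.

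Chromosome 2 held 2.71 hTSC-only peaks per hESC-only peak. A few trophoblast loci are argued against, since 96% of its 10 Mb windows (24 of 25) exceeded the ratio of the other autosomes, against a median of 42.9% on those. All windows did so on chromosomes 21 (4 of 4) and 22 (5 of 5), as did 85.7% on chromosome 20, and at most 77.8% on the rest. A high share of windows is therefore not particular to chromosome 2. At equal list lengths the ratio of ratios was 1.55 (1.48 to 1.63), so the excess was not confined to the weakest hTSC peaks. This decides little about a longer hTSC list as the cause. Dividing by the other autosomes already removes an effect of length that all chromosomes share. More reads from the whole chromosome in hTSC, as with a gained copy in culture, may raise the local background and so lower the fold of peaks near the threshold: the chromosome 2 to other autosome ratio of that fold, hTSC over hESC, was 0.923 (0.912 to 0.934), but chromosomes 19 and 22, without a like excess, had a lower hTSC fold still, against what the test required. Their hESC fold was low too. After division by it, a step added once that was known, chromosomes 2 (0.974) and 20 (0.981) were lowest, with 1.01 to 1.08 on the other 20 autosomes. Chromosome 21, with 2.13 hTSC-only peaks per hESC-only peak, had 1.025, inside that range. Its hTSC median fold, 3.92, was the same value as on most autosomes, where the divided value varies with the hESC fold alone. The measure is therefore coarse and decides little for chromosome 21. The step was also chosen on these values, so the explanation stays open.

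Long genes carried relatively more hESC-only peaks. In 315 genes of at least 500 kb there were 2958 hESC-only and 2923 hTSC-only peaks, against 13207 and 25657 in shorter genes, a ratio of ratios of 0.509 (0.481 to 0.538), which argues against chance in proportion to gene length. Weak peaks near the authors' threshold are argued against by 0.490 (0.453 to 0.529) with −log10 q of at least 10. The long genes then held more hTSC-only (1869) than hESC-only peaks (1244), against 18303 and 5969 in shorter genes, so their hESC lean is only relative to shorter genes. A difference between the cell types themselves and differences in depth or library quality between them stay open and were not tested.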
